A study of Mus musculus with 13 samples.

How the data were processed

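The series holds 13 samples from skeletal muscle of C57BL/6 wild-type mice aged 2 months, in 5 groups. Of these, 11 were bulk RNA-seq libraries made with a Smart-seq2 type polyA protocol, in which full-length cDNA is copied from few cells. They comprised 3 libraries of freshly sorted SMMC, 3 of SMMC cultured for 3 days and still proliferating, 3 of SMMC that had been cultured and allowed to differentiate, and 2 of freshly sorted MuSC. MuSC are muscle stem cells, sorted as CD31-negative, CD45-negative, Sca1-negative, VCAM1-positive and ITGA7-positive. SMMC are smooth-muscle and mesenchymal-like cells, sorted with the same antibodies as ITGA7-positive but VCAM1-negative. The remaining 2 samples were droplet single-cell libraries (10x 3' chemistry) of mononuclear cells from uninjured muscle. The genes behind the 5 antibodies are Pecam1 (CD31), Ptprc (CD45), Ly6a (Sca1), Vcam1 and Itga7.

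The bulk values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 value per gene symbol, per the file headers and as the authors deposited them. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.3.1, StringTie, STAR 2.5.1b, Cell Ranger 2.1.0 and 2.2.0, Seurat 2.2 and 2.3.4 and R 3.3.1, 3.4.3 and 3.5.1 were used with genome build mm10, without a statement of which tool made which table. The gene annotation, the strand setting and the treatment of reads that fit several genes were not given in the sources used here, so overlapping genes, near-identical family members such as the histone genes and antisense partners are uncertain. The table held 24411 genes, of which 2858 were at 0 in all 11 libraries. It also held 4 FPKM columns that matched no sample, and these were not used. FPKM keeps no read count, and the low values showed no common step: among 1817 genes below 0.3 FPKM in fresh SMMC replicates 1 and 2, the most common bin of ratios, 0.01 log2 wide, held 0.936%. The depth of the bulk libraries is therefore unknown, and their precision was judged only from the spread between libraries.

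The single-cell values were UMI counts per gene and cell, per the values in the deposited tables, which held whole numbers from 0. The first library had 6144 cells, 19353328 UMIs and a median of 2516 UMIs per cell. The second had 6297 cells, 15507938 UMIs and a median of 2027. The cell and gene filters that the authors applied before deposit were not given in the sources used here. The labels number the libraries within each group but do not say that they come from separate animals, so p-values measure only the spread between these samples, which may be technical.

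Bulk genes with at least 1 FPKM in at least 2 libraries were tested, which left 13233. The test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) on log2(FPKM + 1), with 1 mean per group, all 11 libraries in one fit and 7 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The 3 comparisons were fresh SMMC against MuSC, proliferating against fresh SMMC, and differentiating against proliferating SMMC. The fresh and the proliferating libraries each enter more than one of them.

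Before the data were examined, 19 gene lists were fixed: skeletal muscle stem cell, myogenic differentiation, smooth muscle contractile, pericyte, fibro-adipogenic progenitor, extracellular matrix, cell cycle, Notch pathway, TGF-beta and YAP response, immediate early and heat shock, cholesterol synthesis, glycolysis, interferon response, adipogenic, bone and cartilage, endothelial, blood cell, Schwann cell and tenocyte genes. Lists were tested with limma's camera at its preset correlation of 0.01, which compares a list with all other genes tested, and adjusted over the 19 lists within a comparison. Camera with a correlation estimated from the data was run as an alternative. fry, which asks whether the members of a list move on balance one way and does not compare the list with other genes, was run as another tool.

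The genes named were set by a rule also fixed before the data were examined. For each bulk comparison they were the 5 sort genes; the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean of at least 10 FPKM in the higher group and no overlap between the groups, without predicted, mitochondrial and haemoglobin genes; and from each list up to 3 members with the smallest adjusted p in the direction of most called members. Rn45s, Pax7, Myod1, Myog, Mki67, Acta2 and the list members named because few of their list moved with or against it were chosen after their values were seen. Some genes that this rule selects are not reported here.

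In each single-cell library, cells with at least 200 genes and at most 20% mitochondrial counts were kept, which removed no cell. Doublets called by Scrublet, as carried in scanpy 1.11.5, were removed: 52 cells in the first library (0.846%) and 4 in the second (0.0635%). So few calls may mean that the caller failed or that doublets had been removed before deposit, which was not tested, and removal of the 5% of cells with the highest doublet scores was added as an alternative after seeing this. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes without the 5 sort genes, 30 principal components, 15 nearest neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.0 gave 24 clusters in each library. Clusters were named from 15 marker lists fixed before the data were examined and free of the sort genes. A name required at least 3 markers and at least 50% of the measured markers to be 2-fold higher than in other cells, with 10 CPM (UMI counts scaled to the total of the summed cells) added, and seen in at least 10% of the cells. A cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed. These naming thresholds were set after the clusters had been seen. They left 1.61% of cells unnamed in the first library and 4.12% in the second, among them a cluster of 116 cells of the second library led by Il1b, Lyz1, Retnla and Cd209a that an earlier form of the naming had called macrophage or monocyte-like. Smooth muscle-like and pericyte-like clusters were pooled as mural cells, the contractile cells of vessel walls.

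Sort genes were compared between classes with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors) on counts summed per library and class. The fit held 20 sums of the 10 classes with at least 20 cells in both libraries, with the library as a block, 9 residual degrees of freedom and 11975 genes. The sums are not independent animals. Adjustment covered 15 tests, of 5 genes against 3 classes. Intervals are exact, at 95%, binomial for shares and Poisson for CPM, and cover counting error only. A count of 0 was taken to allow up to 3. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs. Genes called in bulk were followed in the single cells as the median log2 ratio of summed counts (0.5 count added), set against 10000 random lists of the same size matched on mean expression in 20 bins.

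Gene positions come from the GRCm38 assembly and GENCODE release M21, with coordinates counted from 1. GRCm38 is the assembly behind mm10. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used. The bulk test was tested on simulated values of the 13233 genes: for fresh SMMC against MuSC it recovered 29.9% of 2-fold, 95.5% of 4-fold and 100% of 8-fold changes; for proliferating against fresh SMMC 58.2%, 98.5% and 100%; and for differentiating against proliferating SMMC 41.8%, 100% and 100%. The test of mural against MuSC sums, simulated on 10830 genes, recovered 5.97%, 76.1% and 97.0%. That simulation adjusted over all 10830 genes and not over the 15 sort gene tests. It therefore does not show how often those 15 tests find such changes.

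Alternatives fixed before the data were examined were a pseudocount of 0.1 FPKM, no filter or a filter at 10 FPKM, TMM rescaling, quantile normalization, no intensity trend, only the groups compared, the replicate number as a block, an estimated correlation between genes, and leaving out each library in turn; for the single cells, Leiden resolutions of 0.5 and 2.0, doublets kept, a stricter filter at 500 genes and 10% mitochondrial counts, the sort genes kept in the clustering, no library block, library sizes in place of TMM factors, and only bulk genes called with at least a 2-fold change. Added after seeing the data were removal of Rn45s with columns set to one total, removal of each library's trend on transcript length (lowess span 0.3), and the doublet score limit.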

Results

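Gene expression in mouse skeletal muscle was measured in bulk in 11 libraries of sorted cells and in 2 droplet single-cell libraries of muscle mononuclear cells. The bulk groups were fresh SMMC (n = 3), proliferating SMMC after 3 days of culture (n = 3), differentiating SMMC (n = 3) and fresh MuSC (n = 2). Libraries of one group ranked genes alike, with Spearman's rho across genes between 0.949 and 0.981 within groups, although genes are not independent replicates. Between fresh SMMC and MuSC rho ran from 0.672 to 0.705, between fresh and proliferating SMMC from 0.598 to 0.631, and between proliferating and differentiating SMMC from 0.833 to 0.887. Genes at 1 FPKM or more numbered 11512 ± 222 in fresh SMMC, 10087 ± 229 in proliferating SMMC, 10633 ± 89.8 in differentiating SMMC (SD, n = 3 each) and 9687 ± 226 in MuSC (SD, n = 2). Rn45s, the precursor of ribosomal RNA, was the most abundant entry in all 9 SMMC libraries, at 44109 ± 8928 FPKM in the fresh, 41662 ± 15846 in the proliferating and 35721 ± 8638 in the differentiating ones, against 118 ± 6.88 FPKM in MuSC. In the MuSC libraries the most abundant gene was Sdc4, a membrane proteoglycan of muscle stem cells, with 5.29% and 7.93% of all FPKM.

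The first comparison asked how the freshly sorted ITGA7-positive, VCAM1-negative cells differ from muscle stem cells sorted as positive for both. Fresh SMMC libraries carried high levels of genes of contractile vessel wall cells, of tendon and of glia, and low levels of muscle stem cell genes. Rgs5, a pericyte gene, stood at 1170 ± 448 FPKM in fresh SMMC and 11.3 ± 0.148 in MuSC, and Myh11, the smooth muscle myosin heavy chain, at 61.7 ± 14.8 against 0.670 ± 0.126. Tnmd, a tendon membrane protein, stood at 2935 ± 1465 FPKM against 1.16 ± 0.269, a 1251-fold difference. Myf5, a regulator of the muscle lineage, showed 6.07 ± 2.81 FPKM in fresh SMMC and 1943 ± 953 in MuSC, 271-fold lower. In limma's test 7906 of 13233 genes passed, 5522 higher and 2384 lower in fresh SMMC, of which 4284 and 1757 differed at least 2-fold. With a filter at 10 FPKM, 5233 of 7892 passed.

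The genes that define the sort followed it in part. Vcam1, an adhesion receptor, was 5.10-fold lower in fresh SMMC (22.3 ± 3.35 against 119 ± 33.8 FPKM, limma adjusted p = 3.5e-04). Itga7, the laminin-binding integrin that marked both sorted populations, was 3.16-fold lower in fresh SMMC (48.8 ± 23.9 against 145 ± 30.9 FPKM, limma adjusted p = 0.0154). For both genes all 3 SMMC libraries lay below both MuSC libraries. Pecam1 (14.7 ± 4.29 against 1.76 ± 0.121 FPKM, 5.58-fold, limma adjusted p = 1.5e-05) and Ly6a (15.1 ± 5.23 against 0.576 ± 0.157 FPKM, 9.84-fold, limma adjusted p = 3.1e-05), the genes of 2 antibodies used to exclude cells, were higher in all 3 SMMC libraries than in both MuSC libraries. Ptprc was too low to be tested, with means of 0.0883 FPKM in fresh SMMC and 0.00953 in MuSC. The difference in Itga7 was not called without fresh SMMC replicate 1 (adjusted p = 0.0645), without MuSC replicate 1 (0.113) or without a filter on low values (0.0553).

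The 8 largest increases in fresh SMMC were Tnmd, Thbs4 (5469 ± 1215 against 4.23 ± 1.64 FPKM), Mgp (757 ± 234 against 0.417 ± 0.212), Chad, Dcn (2653 ± 855 against 4.82 ± 2.29), Fmod (380-fold higher), Serpinf1 and Cilp2, many of which encode proteins of tendon or connective tissue matrix. The 8 largest decreases were Sox11 (1.70 ± 0.476 against 1037 ± 471 FPKM, 368-fold lower), Myf5, Spry2 (10.6 ± 3.88 against 2183 ± 587, 193-fold lower), Lrrc8a, Tug1, Igsf3, Frat1 and Nfia. Limma's adjusted p for these 16 genes lay between 3.3e-09 and 2.0e-06, and no SMMC library overlapped a MuSC library.

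**Figure D1:**
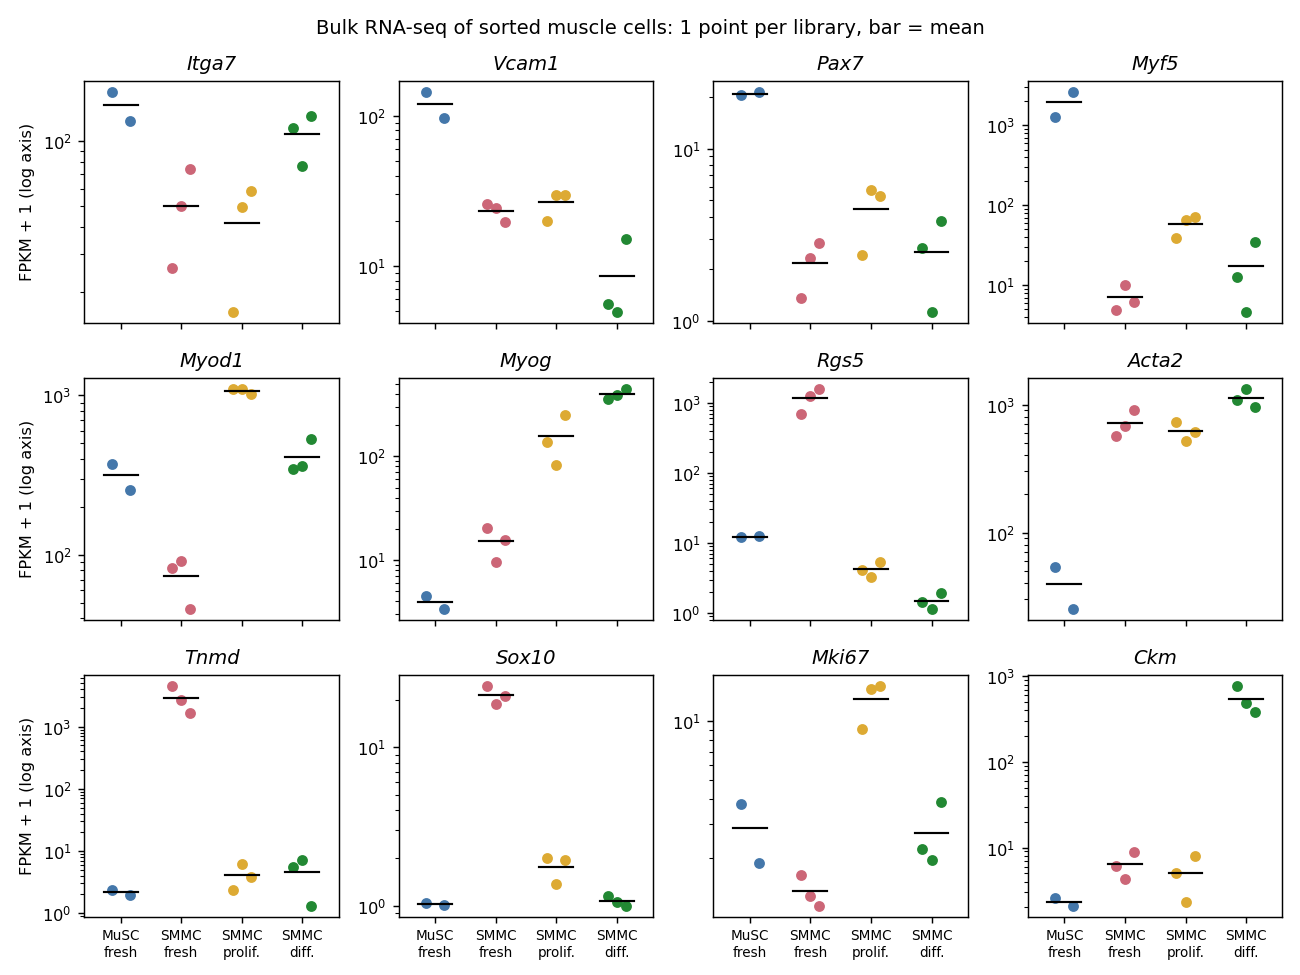
Levels of 12 genes in the 11 bulk libraries, as FPKM + 1 on a log axis, with a point per library and a bar at the mean of each group. Tnmd and Rgs5 were high in the fresh SMMC libraries (means of 2935 and 1170 FPKM), Ckm in the differentiating ones (548 FPKM).

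Camera called 8 of the 19 lists in this comparison, 7 higher and 1 lower in fresh SMMC, and 0 with an estimated correlation (2 at an unadjusted p under 0.05), while fry called 13. Counts of members adjusted over the list alone equalled those over all genes unless given. All 12 tenocyte genes rose (camera adjusted p = 4.8e-06, adjusted p = 0.327 with an estimated correlation), with Comp at 326 ± 133 against 0.410 ± 0.00387 FPKM and Chad at 1001 ± 567 against 1.10 ± 1.10. Of 15 pericyte genes 13 rose (camera adjusted p = 1.4e-05, adjusted p = 0.351 with an estimated correlation), among them Ndufa4l2 (307 ± 140 against 1.14 ± 0.00692 FPKM) and the gap junction gene Gja4 (33.1 ± 8.86 against 0.418 ± 0.126). Smooth muscle contractile genes rose in 14 of 16 cases (camera adjusted p = 2.0e-05, adjusted p = 0.327 with an estimated correlation), with Myl9 73.9-fold and Tpm2 32.5-fold higher. Of 12 Schwann cell genes 11 rose and Egr2 fell (camera adjusted p = 4.4e-04, adjusted p = 0.351 with an estimated correlation). Sox10, a glial transcription factor, reached 20.4 ± 2.86 against 0.0236 ± 0.0268 FPKM. Endothelial genes rose in 10 of 11 cases and Tek fell (camera adjusted p = 0.00358, adjusted p = 0.351 with an estimated correlation), with Esam, a junction protein, at 100.4 ± 35.8 against 1.56 ± 0.167 FPKM and Cldn5 at 28.5 ± 2.53 against 0.451 ± 0.113. At 10 FPKM, where 5 endothelial genes were left and 4 rose, with a larger median log2 change (3.725 against 1.98), the list was not called (camera adjusted p = 0.185).

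Of 19 extracellular matrix genes 14 rose and Serpinh1 fell (camera adjusted p = 0.00620, adjusted p = 0.682 with an estimated correlation), with Col1a2, a collagen I chain, 158-fold and Fn1, fibronectin, 41.2-fold higher. Immediate early and heat shock genes, which respond to cell stress and to tissue dissociation, rose in 13 of 17 cases and Klf4 fell (camera adjusted p = 0.00728, adjusted p = 0.682 with an estimated correlation), with Jun at 1740 ± 226 against 113 ± 56.1 FPKM and Junb at 972 ± 257 against 31.3 ± 0.714. Skeletal muscle stem cell genes fell in 11 of 15 cases (camera adjusted p = 1.5e-05, adjusted p = 0.327 with an estimated correlation), including Sdc4 (483 ± 51.0 against 31275 ± 7889 FPKM), Musk, a receptor of the neuromuscular junction (42.7-fold lower), and Tenm4 (19.6-fold lower), while Chodl and Spry1 were among those that rose.

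The other 11 lists were not called by camera. Of 20 myogenic differentiation genes 9 rose, among them Mef2c (26.6 ± 11.3 against 0.298 ± 0.0314 FPKM), and Myod1 and Chrna1 fell. Of 13 fibro-adipogenic progenitor genes 9 rose, and Dpt and Col15a1 fell. Glycolysis genes rose in 8 of 14 cases, with Tpi1 12.4-fold higher, and 1 fell (2 adjusted over the list alone). Interferon response genes rose in 6 of 15 cases (5 adjusted over the list alone), with Cxcl10 13.0-fold higher. Adipogenic genes rose in 5 of 8 cases, with the fatty acid carriers Fabp4 and Cd36 33.3-fold and 52.8-fold higher. Bone and cartilage genes rose in 6 of 10 cases and fell in 2, and blood cell genes rose in 4 of 7, with Lyz2 at 257 ± 226 against 0.357 ± 0.0420 FPKM, and Cd79a fell. Notch pathway genes rose in 4 of 13 cases (3 adjusted over the list alone), with the Notch targets Nrarp and Hes1 46.5-fold and 46.3-fold higher, and 3 fell. In the TGF-beta and YAP response list 7 of 12 rose and 3 fell, with a positive median log2 change of 1.83 where camera's direction was down. Cholesterol synthesis genes fell in 4 of 15 cases, with Insig1 18.2-fold lower, and 2 rose. Of 20 cell cycle genes 4 rose and 4 fell (2 and 2 adjusted over the list alone). The median log2 change of all genes was 0.45, with 69.9% of called genes higher in fresh SMMC. With TMM rescaling the median was 0.04 and 51.3% of called genes were higher, and with quantile normalization -0.04 and 48.1%.

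**Figure D2:**
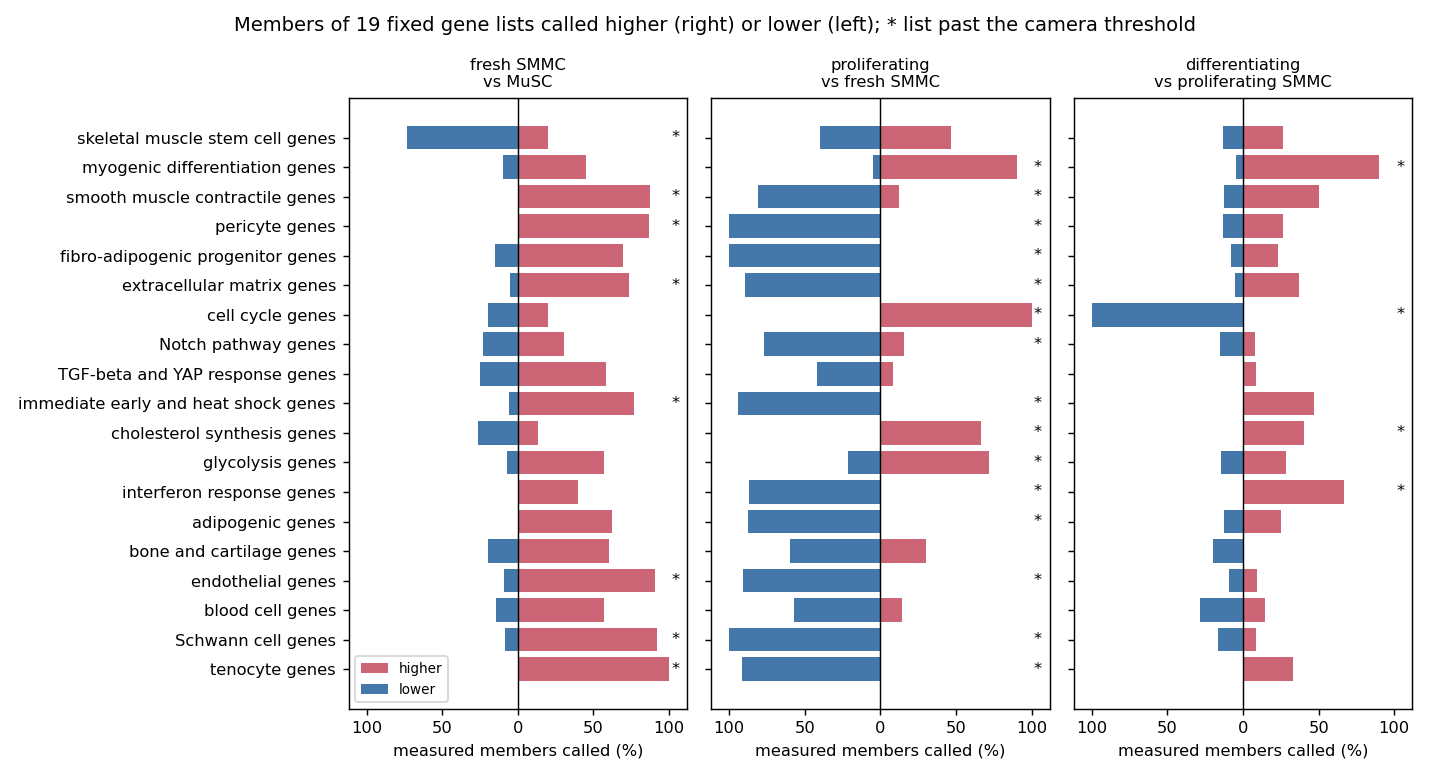
Percent of the tested members of each of the 19 gene lists that limma called higher (to the right) or lower (to the left) in the 3 bulk comparisons, with a star where camera called the list at its preset correlation. Of the cell cycle genes, 20 of 20 were higher in proliferating than in fresh SMMC and 20 of 20 lower in differentiating than in proliferating SMMC.

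The second comparison asked what changed when sorted SMMC were put in culture. After 3 days the libraries had gained cell cycle and skeletal myogenic transcripts and lost those of pericytes, tendon and glia. Rrm2, a subunit of the enzyme that makes deoxynucleotides, rose from 3.09 ± 1.84 to 788 ± 132 FPKM, and Chrna1, the acetylcholine receptor subunit of skeletal muscle, from 4.37 ± 2.75 to 605 ± 72.9. Rgs5 fell from 1170 ± 448 to 3.24 ± 1.02 FPKM, and Tnmd from 2935 ± 1465 to 3.11 ± 1.87. Limma called 9061 of 13233 genes, 4381 higher and 4680 lower in proliferating SMMC, of which 3221 and 3534 changed at least 2-fold. Which direction held more genes depended on the processing: 5039 were higher and 4060 lower with quantile normalization, and at 10 FPKM, where 6030 of 7892 passed, 3431 were higher and 2599 lower.

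The 8 largest increases were Rrm2, Ccnb1 (247 ± 16.5 against 0.670 ± 0.528 FPKM), Hist1h2ap, Ube2c (188 ± 6.95 against 0.532 ± 0.294), Chrna1, Gtse1, Spc24 and Aurka. Apart from Chrna1 these act in DNA replication, chromatin or mitosis. The 8 largest decreases were Thbs4, Steap4 (1.94 ± 1.73 against 3368 ± 1491 FPKM), Fmod, Cxcl1, a chemokine (1.06 ± 0.313 against 1958 ± 235), Hspa1a, an inducible heat shock protein (3.03 ± 0.184 against 3442 ± 1581), Tnmd, Dcn and Chad. For these 16 genes limma's adjusted p lay between 4.5e-10 and 3.0e-07, and the 3 proliferating libraries did not overlap the 3 fresh ones. Of the sort genes, Pecam1 was 10.9-fold lower (0.422 ± 0.172 FPKM, limma adjusted p = 2.7e-07) and Ly6a 2.91-fold lower (4.46 ± 1.57 FPKM, limma adjusted p = 0.00313), each in all 3 libraries. Itga7 (40.6 ± 22.4 against 48.8 ± 23.9 FPKM, 1.26-fold lower, limma adjusted p = 0.540) and Vcam1 (25.5 ± 5.69 against 22.3 ± 3.35 FPKM, 1.13-fold higher, limma adjusted p = 0.691) did not pass, and their libraries overlapped. Ptprc was not tested, at 0 FPKM in the 3 proliferating libraries.

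Camera called 15 lists here, 4 higher and 11 lower, and 0 with an estimated correlation (4 at an unadjusted p under 0.05), while fry called 19. All 20 cell cycle genes rose (camera adjusted p = 1.1e-10, adjusted p = 0.190 with an estimated correlation), such as Plk1 (93.4-fold) and Cdk1 (84.1-fold), both mitotic kinases. Of 20 myogenic differentiation genes 18 rose and Mef2c fell (camera adjusted p = 1.1e-06, adjusted p = 0.245 with an estimated correlation), with Tnni1, a slow fibre troponin, at 376 ± 163 against 3.78 ± 1.16 FPKM. Myod1 stood at 1069 ± 45.8 against 72.3 ± 24.1 FPKM. Glycolysis genes rose in 10 of 14 cases and fell in 3 (camera adjusted p = 0.00353, adjusted p = 0.350 with an estimated correlation), with Eno1 16.7-fold and Pkm 10.7-fold higher. Cholesterol synthesis genes rose in 10 of 15 cases (camera adjusted p = 0.0182, adjusted p = 0.366 with an estimated correlation), with Fdps 3.94-fold higher. The cholesterol synthesis call was lost at 10 FPKM (camera adjusted p = 0.0932).

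All 15 pericyte genes fell (camera adjusted p = 7.5e-08, adjusted p = 0.190 with an estimated correlation), Ndufa4l2 from 307 ± 140 to 0.0937 ± 0.0199 FPKM and Vtn from 181 ± 78.3 to 0.0603 ± 0.0273. Tenocyte genes fell in 11 of 12 cases, Scx not passing (camera adjusted p = 8.2e-07, adjusted p = 0.190 with an estimated correlation), with Kera 409-fold lower. All 12 Schwann cell genes fell (camera adjusted p = 1.4e-06, adjusted p = 0.190 with an estimated correlation), with Pmp22 36.0-fold lower. All 13 fibro-adipogenic progenitor genes fell (camera adjusted p = 4.8e-06, adjusted p = 0.190 with an estimated correlation), with Gsn 60.7-fold lower. Extracellular matrix genes fell in 17 of 19 cases (camera adjusted p = 4.8e-06, adjusted p = 0.304 with an estimated correlation), with Col3a1 16.1-fold lower. Endothelial genes fell in 10 of 11 cases (camera adjusted p = 4.4e-05, adjusted p = 0.190 with an estimated correlation), with Cldn5 27.5-fold lower. Immediate early and heat shock genes fell in 16 of 17 cases (camera adjusted p = 3.6e-08, adjusted p = 0.190 with an estimated correlation), Fos from 1383 ± 263 to 3.78 ± 0.784 FPKM.

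Smooth muscle contractile genes fell in 13 of 16 cases (camera adjusted p = 0.00118, adjusted p = 0.245 with an estimated correlation), with Myh11 59.1-fold and Mylk 79.9-fold lower, while Tpm2 and Actc1, which skeletal muscle also uses, rose and Acta2 did not pass. Interferon response genes fell in 13 of 15 cases (camera adjusted p = 0.00104, adjusted p = 0.410 with an estimated correlation), with Gbp2 53.3-fold lower. Adipogenic genes fell in 7 of 8 cases (camera adjusted p = 0.00353, adjusted p = 0.190 with an estimated correlation), with Fabp4 92.6-fold lower. Notch pathway genes fell in 10 of 13 cases, and Dll1 and Lfng rose (camera adjusted p = 0.0189, adjusted p = 0.350 with an estimated correlation), with Notch3 58.4-fold lower. Not called by camera were the skeletal muscle stem cell list, in which 7 of 15 rose (9 adjusted over the list alone), such as Cdh15 (60.3 ± 16.9 against 3.44 ± 1.70 FPKM), and 6 fell, with a positive median log2 change of 0.88 and a mean of -0.24; the TGF-beta and YAP response list (Ankrd1 rose and 5 of 12 fell, with Tgfbi 49.0-fold lower); the bone and cartilage list (3 of 10 rose and 6 fell, with Comp 291-fold lower); and the blood cell list (Laptm5 rose and 4 of 7 fell, with Lyz2 190.1-fold lower). The median log2 change of all genes was -0.06, against -0.10 with TMM rescaling and 0.14 with quantile normalization. It was -0.20 with Rn45s left out and columns set to one total, changes whose parts were not told apart.

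The third comparison asked what changed when cultured SMMC were allowed to differentiate. Of 20 myogenic differentiation genes 18 rose, and all 20 cell cycle genes fell, with list calls by camera that did not hold with an estimated correlation. Ckm, the muscle creatine kinase, stood at 548 ± 199 FPKM in differentiating and 4.09 ± 2.79 in proliferating SMMC, a 116-fold difference, and Myh8, the perinatal myosin heavy chain, at 539 ± 143 against 7.03 ± 8.48, 94.2-fold. Rrm2 fell 13.1-fold, to 65.3 ± 34.9 FPKM from 788 ± 132. Limma called 5360 of 13233 genes, 2769 higher and 2591 lower in differentiating SMMC, of which 1816 and 1450 changed at least 2-fold. This balance also turned, to 2460 higher and 2960 lower with quantile normalization and 1838 and 2018 at 10 FPKM.

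The 8 largest increases were Msln (837 ± 78.2 against 1.99 ± 1.09 FPKM, 292-fold), Ckm, Ankrd23, Fgf21, a hormone that muscle can secrete (173 ± 58.8 against 0.739 ± 0.483), Myh8, Casq1, the calcium store protein of skeletal muscle (619 ± 117 against 7.19 ± 6.28), Ckmt2 and Tceal7. The 8 largest decreases were Sct (0.139 ± 0.0988 against 53.5 ± 9.91 FPKM), Adgrg3, Sp7, a regulator of bone formation (0.105 ± 0.136 against 43.1 ± 9.45), Dlx2, Hist2h3c1, Fam19a5, Hist1h2ao and Rrm2. Limma's adjusted p for these 16 genes lay between 5.8e-09 and 3.0e-04, with no overlap between the groups. Of the sort genes, Itga7 was 2.89-fold higher (106 ± 27.3 against 40.6 ± 22.4 FPKM, limma adjusted p = 0.0202) and Vcam1 3.49-fold lower (7.58 ± 5.77 against 25.5 ± 5.69 FPKM, limma adjusted p = 0.00200) in all 3 differentiating libraries. Ly6a (10.7 ± 6.24 against 4.46 ± 1.57 FPKM, 2.01-fold higher, limma adjusted p = 0.0526) and Pecam1 (0.244 ± 0.422 against 0.422 ± 0.172 FPKM, 1.18-fold lower, limma adjusted p = 0.521) did not pass, and Ptprc was not tested, at means of 0.00140 and 0 FPKM. The Itga7 call was lost without proliferating replicate 1 (adjusted p = 0.0684), without differentiating replicate 1 (0.0624) or 3 (0.0610), with only the compared groups in the fit (0.0687) and without a filter on low values (0.0737).

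Camera called 4 lists, 3 higher and 1 lower, and 0 with an estimated correlation (2 at an unadjusted p under 0.05), while fry called 8. All 20 cell cycle genes fell (camera adjusted p = 1.7e-13, adjusted p = 0.474 with an estimated correlation), with Mcm7, part of the replicative helicase, 8.27-fold and Cdc20 6.40-fold lower. Myogenic differentiation genes rose in 18 of 20 cases and Myod1 fell (camera adjusted p = 4.5e-12, adjusted p = 0.474 with an estimated correlation), with Myl4 at 2989 ± 273 against 73.0 ± 46.0 FPKM and Mef2c at 297 ± 28.1 against 8.72 ± 5.12. Cholesterol synthesis genes rose in 6 of 15 cases (camera adjusted p = 0.00949, adjusted p = 0.886 with an estimated correlation), with Dhcr7 3.89-fold higher. Interferon response genes rose in 10 of 15 cases (12 adjusted over the list alone; camera adjusted p = 0.00986, adjusted p = 0.886 with an estimated correlation). Among them Gbp2 rose by 1.81 on the log2 scale, while the libraries of the groups overlapped for Oasl2 and Ifit1. The count of 10 interferon response genes fell to between 0 and 4 under 8 alternatives, among them leaving out any one of 5 of the 6 libraries. The interferon call was lost without differentiating replicate 2 (adjusted p = 0.104), with only the compared groups in the fit (0.0590) and at 10 FPKM (0.124), and without differentiating replicate 3 camera called 8 lists.

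The other 15 lists were not called by camera. Smooth muscle contractile genes rose in 8 of 16 cases, with Actc1 8.82-fold and Tpm2 7.15-fold higher, and Myl9 and Cald1 fell. Extracellular matrix genes rose in 7 of 19 cases, with Lox 6.95-fold higher, and Serpinh1 fell. Immediate early and heat shock genes rose in 8 of 17 cases, with Egr1 3.90-fold higher. Pericyte genes rose in 4 of 15 cases, with Abcc9 10.9-fold higher, and Rgs5 and Rgs4 fell. Of 15 skeletal muscle stem cell genes 4 rose and 2 fell, with a median log2 change of -0.32 where camera's direction was up. Glycolysis genes rose in 4 of 14 cases (5 adjusted over the list alone), with Aldoa at 5346 ± 555 against 1949 ± 195 FPKM, and 2 fell. Tenocyte genes rose in 4 of 12 cases (3 adjusted over the list alone), fibro-adipogenic progenitor genes in 3 of 13 with 1 falling, and adipogenic genes in 2 of 8 with 1 falling. Bone and cartilage genes fell in 2 of 10 cases, which were Sp7 and Runx2. Blood cell genes rose in 1 of 7 cases and fell in 2, Schwann cell genes rose in 1 of 12 and fell in 2, and Notch pathway genes rose in 1 of 13 and fell in 2, with Lfng 11.8-fold lower. In the TGF-beta and YAP response list Pmepa1 rose of 12 genes. Among 11 endothelial genes Emcn rose and Egfl7 fell, and neither passed when adjusted over the list alone. The calls of Gbp2, Oasl2, Ifit1, Emcn and Pmepa1 were each lost under 1 to 5 alternatives. Those of Cd34 and Mfap5, among the fibro-adipogenic progenitor genes that rose, were each lost under 7.

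The single-cell libraries showed which cells of uninjured muscle carry the transcripts behind the sort. Endothelial-like cells made up 25.4% ± 3.45 of cells, B cell-like cells 23.6% ± 7.90, T or NK cell-like cells 13.2% ± 1.06, fibro-adipogenic progenitor-like cells 11.9% ± 1.99, MuSC-like cells 7.71% ± 2.08, tenocyte-like cells 6.59% ± 2.05, mural cells 4.21% ± 1.01, macrophage or monocyte-like cells 2.24% ± 0.896, glial-like cells 0.834% ± 0.506, neutrophil-like cells 0.495% ± 0.205 and skeletal muscle fibre-like cells 0.202% ± 0.00679 (SD over 2 libraries). Dendritic-like cells were named in the first library only (82 cells), and mast and erythroid cells in neither library, which sets no bound on the share of cells too few to form a cluster. Mural cells numbered 213 in the first library (95% interval of the share 3.05 to 3.99%), where they formed a single pericyte-like cluster led by Acta2, Myl9 and Kcnj8. In the second library they numbered 310 (4.93%, 4.40 to 5.49%), in a pericyte-like cluster of 189 cells and a smooth muscle-like cluster of 121 cells in which the chemokine gene Ccl19 was among the leading genes. In the first library a cluster of 11 cells led by Ccl19 stayed unnamed, so the mural class may not hold the same cells in both libraries.

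Itga7 transcripts were most concentrated in mural cells, which reached 211 ± 95.4 CPM (UMIs scaled to the total of each class and library), against 56.7 ± 7.06 in MuSC-like cells (3.04-fold, edgeR adjusted p = 0.00864), 3.66 ± 3.23 in fibro-adipogenic progenitor-like cells (edgeR adjusted p = 1.5e-07) and 1.38 and 3.08 CPM in endothelial-like cells of the first and second library (edgeR adjusted p = 1.2e-07), each higher in 2 of 2 libraries. The edgeR adjusted p against MuSC-like cells was 0.0558 without the library block. Vcam1 went the other way, at 36.0 ± 16.5 CPM in mural and 618 ± 147 in MuSC-like cells, 25.6-fold lower (edgeR adjusted p = 1.5e-06; 24.3 against 722 CPM in the first and 47.7 against 514 in the second library). It was also 10.1-fold lower than in endothelial-like cells (361 ± 346, with 117 CPM in the first and 605 in the second library, edgeR adjusted p = 6.8e-05), and against fibro-adipogenic progenitor-like cells (70.4 ± 18.8, a log2 difference of -1.32) it did not pass (edgeR adjusted p = 0.0704, lower in 2 of 2 libraries).

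Pecam1 and Ly6a, the genes of 2 antibodies used for exclusion, had intermediate transcript levels in mural cells. Pecam1 reached 158 ± 20.4 CPM there, 5.75-fold above MuSC-like cells (24.4 ± 23.0, with 8.17 CPM in the first and 40.7 in the second library, edgeR adjusted p = 5.3e-05) and 7.16-fold below endothelial-like cells (978 ± 51.0, edgeR adjusted p = 4.8e-06). Ly6a reached 308 ± 36.7, 7.71-fold above MuSC-like cells (32.9 ± 20.2, with 18.6 CPM in the first and 47.1 in the second library, edgeR adjusted p = 1.5e-06) and 6.80-fold below fibro-adipogenic progenitor-like cells (1712 ± 562, edgeR adjusted p = 1.5e-06), in 2 of 2 libraries. Ptprc did not differ past the threshold in any of its 3 tests. In all, 11 of 15 tests passed. Cdh5, an endothelial gene, was also seen in mural cells, at 205 and 123 CPM in the first and second library, against 1113 and 867 in endothelial-like, 4.38 and 29.9 in B cell-like and 23.6 and 36.6 in tenocyte-like cells. Whether doublets or RNA from other cells supplied the Cdh5, Pecam1 or Ly6a transcripts of mural cells was not tested.

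**Figure D3:**
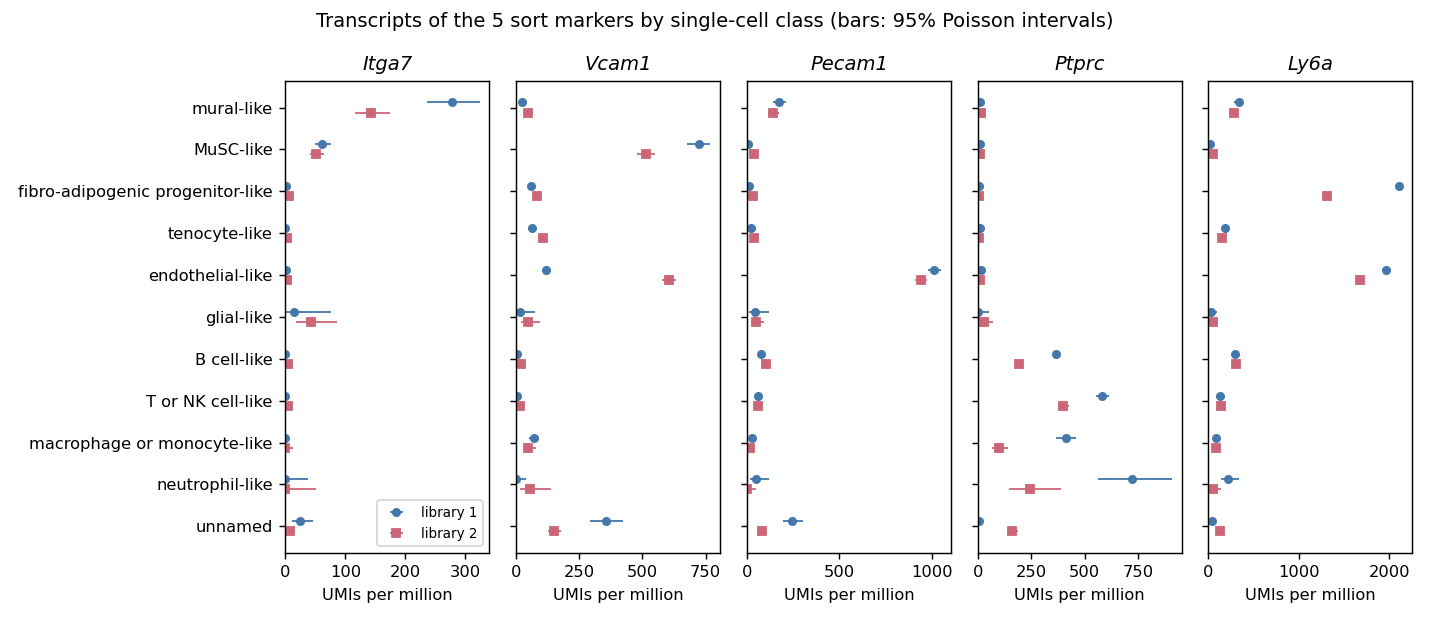
CPM of the 5 sort genes in each cell class with at least 20 cells in both libraries, with a point per library and an exact 95% Poisson interval that covers counting error only. Itga7 was highest in mural cells (278 and 143 CPM) and next in MuSC-like cells (61.6 and 51.7), while Vcam1 was low in mural and high in MuSC-like cells.

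Mural and MuSC-like cells together held most Itga7 UMIs, at 61.1% and 31.7% of 262 UMIs in the first library and 39.7% and 34.2% of 234 in the second. An Itga7 UMI was found in 46.9% and 26.1% of mural cells (median depths of 2133 and 1733.5 UMIs) and in 19.2% and 12.1% of MuSC-like cells (3439.5 and 2531). B cell-like cells, which should lack the gene, had one in 0 of 1780 cells in the first library, which allows up to 0.169%, and in 0.704% of cells in the second (2185 and 1558.5 UMIs). Thinned to 1000 UMIs, the shares were 27.4% and 13.1% of mural, 5.84% and 4.59% of MuSC-like and 0.535% of second-library B cell-like cells. Thinning left out 12 and 19 mural, 3 and 11 MuSC-like and 9 and 14 B cell-like cells. Itga7 thus took a larger share of UMIs in mural than in MuSC-like cells, whereas the bulk SMMC libraries had less than the bulk MuSC libraries.

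On GRCm38, Itga7 lies on chromosome 10 from 128933818 to 128958282, Vcam1 on chromosome 3 from 116109949 to 116129688, Pecam1 on chromosome 11 from 106654217 to 106750628, Ptprc on chromosome 1 from 138062861 to 138175708 and Ly6a on chromosome 15 from 74994877 to 74998031, all protein-coding genes.

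The last comparison asked whether the genes called in bulk differ the same way between mural and MuSC-like single cells. Genes called higher in fresh SMMC had a median log2 ratio of mural over MuSC-like counts of 1.08 in the first library (3925 genes) and 0.68 in the second (3811 genes), above all 10000 random lists. Genes called lower had medians of -0.22 (1752 genes) and -0.62 (1766 genes), below all 10000 random lists. The medians of every other class over MuSC-like cells lay beyond all random lists in the same way. Across genes, Spearman's rho between the bulk and the single-cell change was 0.482 and 0.479, and genes are not independent replicates. The relation was not particular to mural cells: rho was 0.496 and 0.499 with tenocyte-like, 0.443 and 0.476 with fibro-adipogenic progenitor-like, 0.318 and 0.343 with endothelial-like, 0.306 and 0.387 with glial-like and 0.113 and 0.208 with B cell-like cells over MuSC-like cells.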

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

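The counts in this part were all looked at only after the clusters had been seen. In each single-cell library an unnamed cluster was led by Sfrp5, with Apod, Sbspon, Gpc3, Rdh10 and Il33 also among the leading genes of both. Neither cluster entered a comparison, and the share of cells with an Itga7 UMI exceeded the limit that a count of 0 allows in both, which needs only 4 such cells. In the first library 6 of 47 cells had an Itga7 UMI, 12.8% (95% interval 4.83 to 25.7%, limit 6.38%, median depth 2633 UMIs). In the second library 4 of 84 cells did, 4.76% (1.31 to 11.7%, limit 3.57%, median depth 2700.5 UMIs). Thinned to 1000 UMIs, the shares were 2.17% and 2.44%, under those limits. Fibro-adipogenic progenitor-like cells, at median depths of 5579.5 and 3756.5 UMIs, had an Itga7 UMI in 0.617% and 2.27% of cells, the latter inside the interval of the second cluster. The clusters carried 5 of the 12 fibro-adipogenic progenitor markers, too few for that name, and no explanation was tested.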

How the results depend on the processing

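Removal of Rn45s, removal of the transcript length trend and the doublet score limit were chosen after the data were seen. Of 134 values of the main results under the alternatives, 128 stayed within their limits and 6 moved. Another 10, from leaving out 1 of 2 single-cell libraries, stay within 1 SD by construction and show nothing about stability. For calls the limits bound only the total number, whichever genes were called. For fresh SMMC against MuSC, 6510 calls with TMM rescaling and 6093 with quantile normalization were shared with the main 7906. Genes called lower there went from 2384 to 3928 and 4027. At 10 FPKM the called genes numbered 5233 (fresh SMMC against MuSC) and 6030 (proliferating against fresh), with 7892 genes tested, which lowers the count by construction. An estimated correlation left 0 called lists in each of the 3 comparisons by camera (fry called 13, 19 and 8), with lowest adjusted p of 0.327, 0.190 and 0.474. Without differentiating SMMC replicate 3, camera called 8 lists in the third comparison in place of 4, and the cause was not tested. With 1 library left out, called genes ranged from 6454 to 7676, 8330 to 8773 and 4290 to 5085 in the 3 comparisons, and called lists were 8 to 8, 15 to 15 and 3 to 8. Without MuSC replicate 1 or 2 the remaining one was assumed to vary like the other groups. With 1 single-cell library, mural cells made up 3.496 to 4.93%, MuSC-like cells 6.24 to 9.18% and named cells 95.9 to 98.4% of cells, and the medians of bulk-called genes ran from 0.68 to 1.08 (higher) and from -0.62 to -0.22 (lower). These medians replaced their difference as the value compared, after several settings had moved that difference. Results named singly were less stable: 17 of 208 results of named bulk genes lost their call under at least 1 alternative and 1 gained one, 3 of 57 lists lost and 10 gained a call (the estimated correlation, which ended all list calls, set aside), and 1 of 15 sort gene tests lost its call. The 48 other values of shares, not fixed by construction, kept within the spread between libraries. Some of the settings could move them little. The stricter filter kept 6089 of 6144 and 6296 of 6297 cells, and keeping doublets returned only 52 and 4 cells. With the earlier cluster naming, in contrast, the macrophage or monocyte-like share had moved under several settings. No direction of a called value reversed under the alternatives run. However, the majority among called genes changed sides with quantile normalization in all 3 comparisons, and at 10 FPKM or without proliferating replicate 1 in both comparisons of cultured cells. The shares of 49.99%, 50.03% and 48.35% higher after removal of the length trend were set by the centring of each library in that step.

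With the replicate number as a block, limma called 7642, 9039 and 5293 genes and camera 9, 15 and 5 lists. Only 1 of 9 same-numbered pairs of SMMC libraries deviated together at r above 0.1 (-0.128 to 0.142), r was 0.0882 for MuSC with fresh SMMC, and 1 of 9 libraries correlated best with its own number. The values thus gave no sign of pairing by number, but they cannot exclude shared animals or sort days, which the labels do not state. The unknown depth of the bulk libraries limits what can be said of genes below 1 FPKM.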

Other observations

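Of the tests in this part, the one on transcript length was set before its result was seen, and the others, including a second form of the test on tendon transcripts in Itga7-positive single cells, after. In the single-cell libraries, cells with at least 1 Itga7 UMI and no UMI of Vcam1, Pecam1, Ptprc or Ly6a came mostly from the mural and MuSC-like classes. In the first library 64 of 89 such cells were mural (71.9%, 95% interval 61.4 to 80.9%), 20 MuSC-like, 1 glial-like and 0 tenocyte-like (exact upper bound 4.06%). In the second library 44 of 87 were mural (50.6%, 39.6 to 61.5%), 27 MuSC-like, 5 glial-like and 2 tenocyte-like. Cells with UMIs of both Itga7 and Vcam1 and none of the other sort genes were MuSC-like in 47 of 49 and 30 of 36 cases. A missing UMI at this depth does not show that a cell lacks the transcript or the protein.

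Genes specific to single-cell classes (at least 100 CPM and 10-fold above the other named classes with at least 20 cells in both libraries) were compared between fresh SMMC and MuSC. Unnamed cells were left out of this rule, so their genes can count as specific to a named class. Sfrp5, which led an unnamed cluster in each library, counted as glial-specific, and stood at 291 ± 53.5 FPKM in fresh SMMC against 0.745 ± 0.426 in MuSC. All 17 mural-specific genes, 41 of 43 glial-specific genes, 16 of 16 tenocyte-specific genes and 2 of 2 endothelial-specific genes were called higher by limma in fresh SMMC, and 7 of 7 MuSC-specific genes lower. Of the 12 fibro-adipogenic progenitor-specific genes 9 were tested and 7 higher, and of the 27 macrophage or monocyte-specific genes 6 were tested, 2 higher and 1 lower. Of 17 B cell-specific genes 3 were tested, 1 higher and 2 lower, of 10 T or NK cell-specific genes 1, which was not called, and of 20 neutrophil-specific genes 2, both higher. Among the 3 fresh libraries, 15 of 16 tenocyte-specific genes were highest in replicate 1 and lowest in replicate 3, while 15 of 17 mural-specific genes were highest in replicate 3 and lowest in replicate 1.

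The first pattern was the high tendon expression in fresh SMMC, with Thbs4 at 5469 ± 1215 FPKM, Fmod at 3012 ± 1015 and Tnmd at 2935 ± 1465, although selection for ITGA7 would remove tenocytes, which had an Itga7 UMI in 0 of 313 and 4 of 506 cells. Of the 12 genes of the fixed tenocyte list, 3 are on other lists and 7 reach 1 FPKM in MuSC. If the Itga7-positive cells made these transcripts themselves, single cells meeting the sort in transcripts would hold them. The ratio of counts of 9 tenocyte-list genes to 29 pericyte-list and smooth muscle-list genes (those on no other list) was there at most 7.219% of the lowest in a fresh SMMC library (8.431% with all members). That argues against it only for cells in which Itga7 transcripts were seen. Sorting went by protein, so ITGA7-positive cells without a seen transcript are not covered. The values also set UMI counts of a 3' protocol against FPKM of a full-length one. Tenocytes carried over in the sort may account for the pattern. Of the 7 tenocyte-specific genes on no fixed tenocyte list (1500015O10Rik, Angptl7, Cpxm2, Itgbl1, Lox, Mfap4 and Timp1), 100% were called higher, a restriction made after all 16 such genes had been seen to be higher. The same would hold if SMMC made the transcripts, so this cannot decide. Tenocyte-specific genes held 3.13% ± 1.17 of FPKM in fresh SMMC, against 3.98% and 3.26% of UMIs in tenocyte-like cells. Mural-specific genes held 0.754% ± 0.274 of FPKM, against 2.55% and 1.61% of UMIs in mural cells, though these are unlike units. Carry-over and its extent stay open, as the test was chosen afterwards and no sort purity was analysed here.

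The second pattern was that 7906 of 13233 genes differed between fresh SMMC and MuSC, with Rn45s at 44109 ± 8928 against 118 ± 6.88 FPKM. Of the calls 69.9% were higher in fresh SMMC, against 51.3% with TMM rescaling and 48.1% with quantile normalization. Both methods bring the libraries to a common level. They therefore take away most of such an excess whatever its source, and cannot tell where it comes from. Removal of each library's length trend also centres the library, so the 49.99% found there was set by the method and says nothing about the excess. Rn45s held 9.48%, 6.89% and 10.2% of FPKM in fresh SMMC replicates 1, 2 and 3. A share of this size cannot lower other genes 2-fold, and 1757 of the 2384 genes called lower differed at least 2-fold. That argues against Rn45s as the cause of those 1757. Of all genes called lower, 95.68% were still called lower without Rn45s and with columns set to one total. This was to be expected from the small share, so the refit adds little. A bias by transcript length is argued against as the whole cause of the calls, since 77.6% of them were kept with their direction after each library's length trend was removed. Whether length adds to the excess was not tested. For a library batch that follows the group, the test was the rank correlation with mural over MuSC-like single cells, which was at least 0.4786. With B cell-like over MuSC-like cells it was 0.113 and 0.208, the former the lowest of any class. Even that value lay above the limit, set afterwards, under which a batch would have been named the whole cause. All classes were also set against the same MuSC-like cells. The test could thus hardly come out for a batch and does not decide. A batch that adds to the difference cannot be told apart from the group, and the difference between the sorted cell types stays among the open explanations.

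The third pattern was the rise of skeletal myogenic genes in cultured SMMC, Myod1 reaching 1069 ± 45.8 FPKM. A candidate explanation is outgrowth of muscle stem cells carried over in the sort, although the selection of VCAM1-negative cells would remove those that carry VCAM1. The 7 genes specific to MuSC-like single cells had a median level in fresh SMMC of 23.03% of that in MuSC, from 0.3125% (Myf5) to 48.07% (Chrdl2). Carried-over cells with the levels of the sorted MuSC would bring each of these genes to at least their share of the RNA. The median is therefore no measure of that share, which the lowest genes, Myf5 and Gal (2.795%), would limit. Cells that had lost these transcripts are not covered, and the growth of a small share in culture was not measured. Both outgrowth and a change of the SMMC themselves stay open, and the design follows no single cell through culture.

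For the counts of calls, the 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. Every other split also mixes both groups, so their difference adds to the spread and few called genes were to be expected there. Part of that difference remains between the mixed groups, so these splits are no picture of chance. Limma called 9061 genes between proliferating and fresh SMMC (9402 at an unadjusted p under 0.05), against at most 0 in the other splits (477 at an unadjusted p under 0.05), so 1 of 10 splits gave as many. Between differentiating and proliferating SMMC it called 5360 (6389 at an unadjusted p under 0.05), against at most 0 (1064 at an unadjusted p under 0.05), again 1 of 10. Camera called 15 lists between proliferating and fresh SMMC against at most 14 in another split, and 4 between differentiating and proliferating SMMC against at most 9, where all 10 splits gave as many.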
